A study of Rattus norvegicus with 14 samples.

How the data were processed

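Serum was collected from 1 female Long Evans pup per litter on postnatal day 8 after maternal exposure to 0 or 3 ppm of PTU in drinking water. Per the labels' protocols, RNA was isolated with a serum and plasma miRNA kit, and libraries were made with the QIAseq miRNA kit with 22 cycles of PCR. This kit carries molecular identifiers, but whether the deposited counts are of molecules or of reads is not given in the sources used here. If they are reads, amplification adds spread between libraries.

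The authors deposited 1 table for the series with 375 mature rat miRNAs. It holds raw counts per library, deposited as whole numbers and not normalized. It also holds the authors' log2 fold change, mean log2 CPM, p-value and FDR per miRNA, and the mean count (a linear signal) of each group as deposited by the authors. edgeR is named in the submitters' processing notes, without a version. The aligner, the miRNA reference, the genome build and the filter on low counts are not given in the sources used here. When checked on the file, the deposited group means equalled the means of the count columns to within 0.005, the FDR column was the Benjamini-Hochberg adjustment of the p-value column over the 375 miRNAs, and 372 of the 375 miRNAs had counts in all 14 libraries. Every listed miRNA had counts in at least 13 libraries and at least 78 counts in all. The totals given here are sums over the listed miRNAs, not the depth of the libraries. The number of miRNAs detected (373 to 375 in control and 375 in PTU libraries) was set by which miRNAs the table lists and is not a measure of complexity.

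Count columns were matched to samples by the identifier in the sample titles, and groups and replicate numbers came from the titles. All 14 columns of counts matched a sample. No pair of libraries in a group was close to sampling noise (the smallest chi-square per degree of freedom over miRNAs was 21.7), so each counted as 1 replicate. The files name no genome build, so no coordinates are given. The RefSeq gene table of rat assembly GRCr8 was used only for gene order: 374 of the 375 miRNAs matched a precursor gene there, and the 45 tested precursors of the Dlk1-Dio3 list all lay on 1 chromosome.

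Counts were analysed with edgeR 4.0.16 in R 4.3.3. miRNAs were filtered with filterByExpr (357 kept, 18 left out), scaled by the trimmed mean of M values (TMM) and tested with the quasi-likelihood test (glmQLFit and glmQLFTest) for PTU against Control, with all 14 libraries and no covariate. Calls used a false discovery rate of 0.05 (Benjamini-Hochberg). Standard errors were the absolute log2 fold change divided by the square root of the F statistic. CPM values are TMM-scaled, and log2 CPM used a prior count of 2. Single values per library were compared with exact two-sided permutation tests over all 3003 splits. The 12 miRNA lists were tested with camera at a preset correlation of 0.01, adjusted over the 12 lists, with an estimated correlation and fry beside it. In the erythroid list, miRNAs made in other tissues too, such as miR-16 and miR-92a, were included.

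The test, the covariates, the lists and most alternatives were chosen before the data were examined. miRNAs were named by a rule fixed then: the pair in the series title, the 5 with the lowest p in each direction (since fewer than 5 passed), for each list up to 4 members past the threshold or else the 3 most abundant, and the 5 most abundant overall. Other miRNAs named in the text were chosen after their values were seen. These include the further erythroid members miR-144-5p and miR-363-3p, other arms of named precursors, and miRNAs that stand apart in 1 library. Alternatives were other scalings (RLE, upper-quartile, none), no filter and a stricter one (10 counts in at least 10 libraries), DESeq2 1.42.0, limma-voom with quality weights (limma 3.58.1), edgeR's likelihood ratio test, covariates, an FDR of 0.1, and each library left out in turn. The exact test, the robust quasi-likelihood fit, the permutation test per miRNA and the list tests under the other fits were added after the data were seen.

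The procedure was tested on simulated data, drawn for 357 miRNAs with the real means, dispersions and library sizes and 60 changed miRNAs in each of 10 runs; 4.67% of calls were false. With no change simulated, 4.72% of miRNAs had an unadjusted p under 0.05.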

Results

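Serum microRNA was profiled by small RNA sequencing in Long Evans rat pups on postnatal day 8. The dams drank water with 0 or 3 ppm of PTU (propylthiouracil, a drug that blocks thyroid hormone synthesis), and the labels call the control pups euthyroid and the exposed pups hypothyroid. There were 8 control libraries and 6 PTU libraries, each from the serum of 1 female pup of its own litter, so the replicates are separate animals. The deposited table held whole-number counts for 375 mature miRNAs. Total counts over these miRNAs ran from 452961 to 2119979 per library. They averaged 1038140 ± 476252 in the control group (SD, n = 8) and 1201590 ± 467678 in the PTU group (SD, n = 6), a difference within the spread between replicates (exact two-sided permutation test on log2 totals, p = 0.417). The title of the series names miR-495 and miR-543-3p, and the comparison asks which circulating miRNAs differ between hypothyroid and euthyroid pups.

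Muscle miRNAs were among the most abundant in the serum of these pups. miR-206-3p, a miRNA of skeletal muscle, took 37.6% ± 1.71 of the counts in the control group (SD, n = 8) and 36.9% ± 5.45 in the PTU group (SD, n = 6). The next most abundant were miR-16-5p, miR-1-3p (also made in striated muscle), miR-199a-3p and let-7c-5p. Their control means were 92440 ± 15454, 73664 ± 17360, 54311 ± 6772 and 52822 ± 11717 CPM (counts scaled to library size; SD, n = 8). The PTU means were 97845 ± 34981, 54725 ± 8625, 44392 ± 7663 and 41794 ± 9846 CPM (SD, n = 6). The 5 most abundant miRNAs of each library together took 64.2% ± 1.7 of the counts in the control group and 61.5% ± 4.05 in the PTU group (exact permutation p = 0.0932, adjusted p = 0.326 over 7 library measures). A count of 3 corresponded to 6.38 CPM in the smallest library and 1.44 CPM in the largest, a floor that covers counting error only.

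No miRNA passed a false discovery rate of 0.05 between the PTU and control groups in either direction. The miRNAs with the lowest p were miR-543-3p, miR-484 and miR-144-3p among those with a higher PTU mean, and miR-181a-1-3p and miR-27b-3p among those with a lower one. The lowest adjusted p was 0.155, for miR-543-3p (edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over 357 tested miRNAs). At an unadjusted p under 0.05 there were 47 miRNAs, 28 higher and 19 lower in PTU, where 17.9 would be expected by chance. The split by direction depended on the scaling. It was 13 higher and 38 lower with upper-quartile factors, which shifted the median of all miRNAs by -0.11 on the log2 scale, and 44 higher and 9 lower with no factors. Other tests called 2 miRNAs (DESeq2) or 3 (edgeR's likelihood ratio test and exact test), all higher in PTU, and limma-voom called none. On counts simulated for this comparison over 357 miRNAs, the test recovered 34.2% of 1.5-fold, 79.1% of 2-fold and 98.4% of 3-fold changes. The simulation changed 60 miRNAs per run, and the adjusted threshold is stricter where fewer change. It also drew the miRNAs independently, with no library standing apart as PTU replicate 6 does below. These shares may therefore be too high for the real libraries.

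The miRNAs named in the series title were both higher in the PTU group, and neither passed the adjusted threshold. miR-543-3p averaged 108 ± 14.1 CPM in PTU serum (SD, n = 6) and 60.1 ± 17.4 CPM in control serum (SD, n = 8). Counts per library ran from 15 to 232. Its log2 fold change was 0.83 ± 0.19 (SE), with a 95% interval of 0.42 to 1.23 and an adjusted p of 0.155 by edgeR. The groups did not overlap: the lowest PTU library had 95.9 CPM and the highest control library 75.9 CPM. Among the 357 miRNAs, only miR-543-3p (higher) and miR-27b-3p (lower) were separated in this way, where 0.238 would be expected by chance. An exact permutation test over all 3003 splits of the libraries, added after the data were examined, gave p = 0.000333 for both, the smallest value it can give, and 0.0594 after adjustment. miR-495 averaged 113 ± 34.7 CPM in PTU (SD, n = 6) and 77.9 ± 16.7 CPM in controls (SD, n = 8). Its log2 fold change was 0.53 ± 0.19 (SE; 95% interval 0.12 to 0.93; adjusted p = 0.258 by edgeR), and all 6 PTU libraries lay above the control median. In the GRCr8 gene table the precursor genes of miR-543 and miR-495 are direct neighbours. The other arm of miR-543, miR-543-5p, showed no such difference. Its log2 fold change was 0.02 ± 0.25 (SE), at a mean of 22.0 CPM over all libraries. Without PTU replicate 2 the log2 fold change of miR-495 was 0.35. Because the title of this series names both miRNAs, these values were not taken as an independent check of it.

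**Figure D1:**
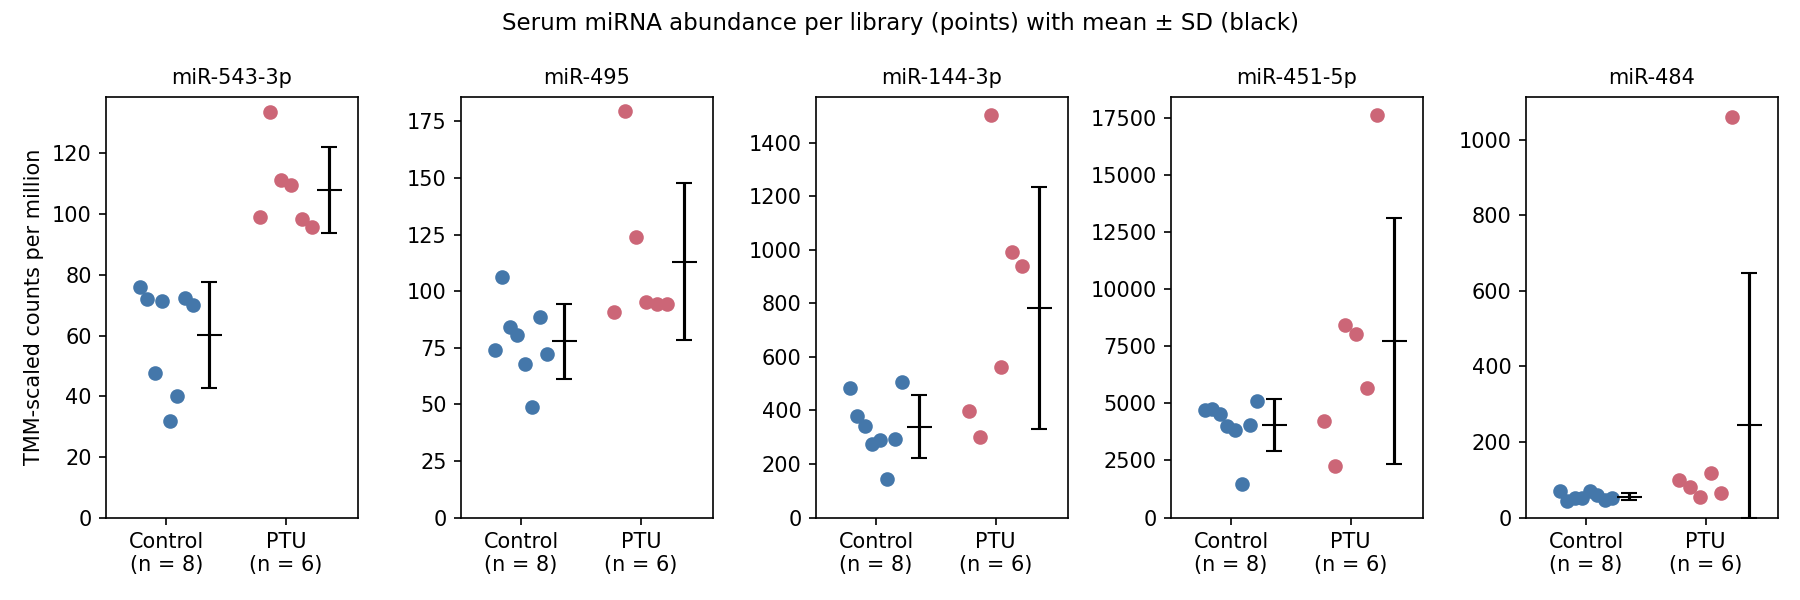
TMM-scaled CPM (linear axes from 0) of 5 miRNAs in the 8 control and 6 PTU serum libraries; points are libraries, black marks the mean ± SD, and the lower arm for miR-484 in PTU stops at 0. The groups do not overlap for miR-543-3p, whereas the PTU mean of miR-484 is set by 1 library at 1061 CPM.

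Among the other miRNAs with a higher PTU mean, miR-484 averaged 246 ± 400 CPM in PTU (SD, n = 6) and 55.7 ± 10.2 CPM in controls (SD, n = 8), a log2 fold change of 2.17 ± 0.58 (SE; adjusted p = 0.179, edgeR). PTU replicate 6 alone had 1504 counts, where no other library had more than 125, and without it the log2 fold change was 0.56 ± 0.20. miR-144-3p, an erythroid miRNA, averaged 784 ± 451 CPM against 340 ± 117 CPM (log2 fold change 1.21 ± 0.32, adjusted p = 0.179, edgeR). miR-103-3p averaged 2195 ± 557 against 1524 ± 162 CPM (0.53 ± 0.15) and miR-362-5p 74.0 ± 12.9 against 44.0 ± 16.5 CPM (0.75 ± 0.23).

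Among miRNAs with a lower PTU mean, miR-27b-3p averaged 2890 ± 281 CPM in PTU (SD, n = 6) and 3750 ± 327 CPM in controls (SD, n = 8), a log2 fold change of -0.38 ± 0.11 (SE; adjusted p = 0.179, edgeR). miR-181a-1-3p averaged 53.9 ± 7.37 against 82.5 ± 18.7 CPM (-0.61 ± 0.17). miR-378b averaged 124 ± 14.3 against 168 ± 23.5 CPM (-0.44 ± 0.14) and miR-299a-3p 275 ± 48.2 against 372 ± 56.5 CPM (-0.44 ± 0.15). In none of the 6 PTU libraries did any of these 4 exceed the control median. miR-203b-3p averaged 123 ± 84.4 against 231 ± 36.5 CPM (-0.91 ± 0.31, adjusted p = 0.257, edgeR). Without PTU replicate 5, the highest of its group at 286 CPM, its log2 fold change was -1.36 with an adjusted p of 0.0058.

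In the authors' deposited table, 3 miRNAs had an FDR below 0.05, all higher in PTU. These were miR-484 (log2 fold change 2.25, FDR 0.0099), miR-543-3p (0.83, FDR 0.0127) and miR-144-3p (1.24, FDR 0.0179) in the authors' deposited table. The authors' deposited table gives miR-495 a log2 fold change of 0.53 with an FDR of 0.283. Across the 357 miRNAs tested here, the deposited and refitted log2 fold changes had a Pearson correlation of 0.999 and the same sign in 355. This correlation is across miRNAs, which are not independent replicates. edgeR's exact test without a filter, added after the deposited table was seen, called these 3 miRNAs as well.

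miRNAs were also grouped into 12 lists by tissue, blood cell or genomic cluster, fixed before the data were examined. For comparison, 206 of all 357 tested miRNAs had a positive log2 fold change, with a median of 0.03. Of the erythroid list, 7 of 7 tested members had a positive log2 fold change in PTU, with a median of 0.82. The list differed from the other miRNAs by camera with a preset correlation (adjusted p = 0.00245) and not with an estimated one (adjusted p = 0.275 with an estimated correlation). fry, which tests for a shift in 1 direction without reference to other miRNAs, gave an adjusted p of 0.163. miR-144-3p, miR-144-5p and miR-451-5p, made from 1 erythroid locus, had log2 fold changes of 1.21 ± 0.32, 1.41 ± 0.46 and 0.93 ± 0.34 (SE). miR-363-3p had 0.82 ± 0.31, miR-451-3p 0.37 ± 0.33, miR-92a-3p 0.36 ± 0.18 and the abundant miR-16-5p 0.08 ± 0.19. Over all miRNAs tested, 0 of the 7 passed; adjusted over the list alone, 4 passed (miR-144-3p, miR-144-5p, miR-451-5p and miR-363-3p). That number was 0 without PTU replicate 3, 1 without Control replicate 6 and 2 without PTU replicate 6. Without PTU replicate 3 miR-144-5p had 0.79 and miR-451-3p 0.13; without PTU replicate 6 miR-451-5p had 0.48 and miR-363-3p 0.28. Without PTU replicate 6 the median was 0.44, without PTU replicate 3 camera's adjusted p was 0.0691, and with the red cell ratio given below as a covariate it was 0.817. The ratio is built on miR-451-5p, a member of the list, so this fit takes out part of the list's own shift by construction. The haemolysis ratio, a usual measure of red cell RNA in serum, is the log2 ratio of miR-451-5p to miR-23a-3p, and it averaged 0.87 ± 0.78 in PTU (SD, n = 6) and 0.12 ± 0.57 in controls (SD, n = 8). This difference of 0.75 did not pass an exact two-sided permutation test (p = 0.0566, adjusted p = 0.326 over the 7 library measures), though without PTU replicate 2 it was 1.03 (p = 0.00155, exact). With any of the 13 other libraries left out it did not pass. The denominator, miR-23a-3p, is in the platelet and endothelial list and had a log2 fold change of 0.07 ± 0.20 (SE). In PTU replicate 6 it was at 7455 CPM, where the median of the other libraries was 3238 CPM, which lowers the ratio of that library.

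**Figure D2:**
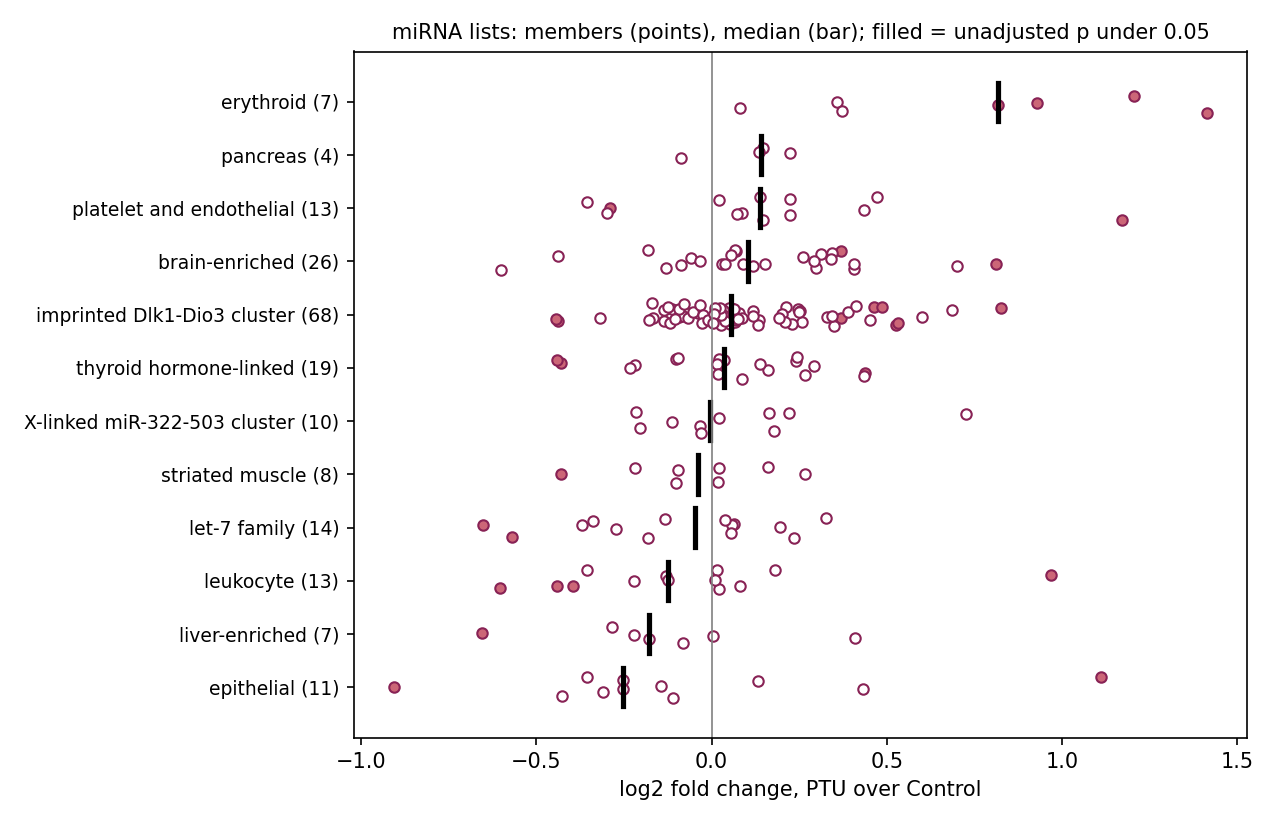
log2 fold change (PTU over Control) of each tested member of the 12 lists (points; number tested in brackets), with the median of each list as a black bar; filled points have an unadjusted p under 0.05. The erythroid median lies at 0.82, and the other 11 medians lie between -0.25 and 0.14.

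Striated muscle miRNAs showed no common direction. Of 8 tested members 4 were higher and 4 lower, with a median log2 fold change of -0.04, and 0.04 with no factors (camera adjusted p = 0.502; adjusted p = 0.82 with an estimated correlation). miR-1-3p, enriched in heart and skeletal muscle, averaged 54725 CPM in PTU against 73664 CPM in controls (-0.43 ± 0.16, unadjusted p = 0.0154 by edgeR, adjusted p = 0.258). miR-133a-3p had -0.22 ± 0.14 and miR-206-3p -0.10 ± 0.12. The list of thyroid hormone-linked miRNAs, which shares 8 muscle miRNAs with the former, had 13 of 19 members higher and a median of 0.04 (-0.06 with upper-quartile factors), while camera's direction was down (adjusted p = 0.843). None of either list passed when adjusted over the list alone with all libraries; without Control replicate 5, 1 passed in each.

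The imprinted Dlk1-Dio3 cluster, a large run of miRNA genes that holds miR-543 and miR-495, showed no common direction. Of 68 tested members 45 were higher and 23 lower, with a median log2 fold change of 0.05 (camera adjusted p = 0.166; adjusted p = 0.82 with an estimated correlation). This median was -0.05 with upper-quartile factors. camera's adjusted p was 0.0295 without Control replicate 2 and 0.0103 without PTU replicate 6 (adjusted p = 0.664 and 0.467 with an estimated correlation). The most abundant members, miR-431, miR-434-3p and miR-382-5p, had log2 fold changes of 0.05 ± 0.13, 0.08 ± 0.14 and -0.11 ± 0.13 (SE), and miR-299a-3p of this cluster was among the lowest at -0.44. Adjusted over the list alone, 1 member passed, miR-543-3p, and 0 passed without Control replicate 3 or 6 or PTU replicate 2 or 3; the title of this series names it, so this was not taken as independent evidence. Brain-enriched miRNAs, which share 4 members with the cluster list, had 19 of 26 higher and a median of 0.10 (-0.0040 with upper-quartile factors; camera adjusted p = 0.166, adjusted p = 0.82 with an estimated correlation). The abundant miR-128-3p had 0.15 ± 0.19, miR-9a-5p 0.34 ± 0.47 (0.18, 0.60, 0.17 and 0.17 without Control replicate 3, 5 or 8 or PTU replicate 4) and miR-487b-3p 0.37 ± 0.17 (adjusted p = 0.356, edgeR). No brain-enriched member passed when adjusted over the list alone. camera's adjusted p for the brain list was 0.0399, 0.0262 and 0.0239 without Control replicate 2, 5 or 6, and 0.0393 with the red cell ratio as covariate. With an estimated correlation the adjusted p in these was 0.664, 0.617, 0.705 and 0.884.

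Epithelial miRNAs were lower in PTU for 8 of 11 tested members, with a median log2 fold change of -0.25. The skin miRNA miR-203a-3p had -0.43 ± 0.23, miR-183-5p -0.31 ± 0.18 and miR-205 -0.11 ± 0.18 (SE). Of the members that were higher, miR-141-3p had 1.11 ± 0.51. In PTU replicate 6 it was at 3441 CPM, where the median of the other libraries was 322 CPM. Without PTU replicate 5, the highest of its group, miR-203a-3p had -0.68, and without Control replicate 5 miR-183-5p had -0.18. None passed when adjusted over the list alone with all libraries, and 2 did without PTU replicate 5. camera gave an adjusted p of 0.049 with a preset correlation and an adjusted p of 0.534 with an estimated correlation, and leaving out any of 7 single libraries (Control replicate 3, 5, 6 or 8 or PTU replicate 1, 3 or 4) also ended the call. Leukocyte miRNAs went both ways. miR-146a-5p, an inducible immune miRNA, had -0.40 ± 0.15, whereas miR-142-3p had 0.97 ± 0.37 and miR-142-5p 0.01 ± 0.23. Without PTU replicate 3 the value for miR-142-3p was 0.47. Adjusted over the list alone, 1 passed, miR-181a-1-3p, and 0 without Control replicate 2, 3, 5, 6 or 7 or PTU replicate 1 or 4. That number was 4 without Control replicate 1, 3 without PTU replicate 3 and 2 without PTU replicate 2 or 5. miR-181a-1-3p is the scarcer arm, with a mean of 70.3 CPM over all libraries. The more abundant miR-181a-5p (1852 CPM) had 0.18 ± 0.17, and miR-181b-5p had 0.01 ± 0.16 (SE). The list passed fry's test for change in either direction (adjusted p = 0.0122) but not camera (adjusted p = 0.102; adjusted p = 0.275 with an estimated correlation). Without Control replicate 2 camera's adjusted p was 0.0399 (adjusted p = 0.272 with an estimated correlation).

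The remaining lists passed none of these tests with all libraries. Liver-enriched miRNAs had 2 of 7 members higher and a median log2 fold change of -0.18. Without PTU replicate 6 the median was -0.28 with 0 of 7 higher, without Control replicate 6 it was -0.028, and with no factors it was -0.058. Its abundant members had -0.22 ± 0.42 (SE) for the hepatocyte miRNA miR-122-5p, -0.08 ± 0.17 for miR-455-5p and 0.0039 ± 0.21 for miR-365-3p; camera's adjusted p was 0.171, but 0.0489 without Control replicate 2 and 0.0313 without PTU replicate 6. Neither call held with an estimated correlation (adjusted p = 0.392 and 0.382 with an estimated correlation, and 0.804 with all libraries). Platelet and endothelial miRNAs had 10 of 13 higher and a median of 0.14 (camera adjusted p = 0.843). Without PTU replicate 6 the median was -0.13, with 3 of 13 higher. Its median was -0.0044 with upper-quartile factors. Adjusted over the list alone, 0 passed with all libraries and 1 without PTU replicate 2, 3, 4 or 5. miR-199a-3p had -0.29 ± 0.13, miR-21-5p 0.09 ± 0.15 and the endothelial miR-126a-3p 0.15 ± 0.19. The let-7 family had 7 of 14 higher and a median of -0.05 (0.06 with no factors; camera adjusted p = 0.339), with -0.34 ± 0.17 for let-7c-5p, -0.37 ± 0.19 for let-7b-5p and 0.06 ± 0.15 for let-7i-5p. Pancreas miRNAs had 3 of 4 higher (median 0.14; camera adjusted p = 0.775), with 0.23 ± 0.21 for miR-7a-5p, -0.09 ± 0.30 for miR-375-3p and 0.14 ± 0.41 for miR-7b. The X-linked miR-322-503 cluster had 5 of 10 higher, a median of -0.0042 and a mean of 0.07, with camera down and fry up (camera adjusted p = 0.843). With no factors the median was 0.07. Its abundant members miR-351-5p, miR-542-3p and miR-542-5p had 0.22 ± 0.23, -0.03 ± 0.18 and -0.21 ± 0.12. Mature sequences within the let-7, miR-7, miR-27, miR-133 and miR-378 families differ by few bases, and reads could be divided among them differently by another counter.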

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

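The tests of red cell RNA, of single libraries, of the scaling, of depth and of the spread of the Dlk1-Dio3 members were chosen after the results they bear on were seen; the tests against the Dlk1-Dio3 cluster median, of miR-223-3p and of other splits of the libraries were set out before. In 17 of 102 groups of values the highest or lowest library stood apart from the rest of its group by Dixon's test, and 5 of the 17 were in PTU replicate 6. Chance gives about 5.1, but the 17 cannot be set against it. miR-222-3p and miR-29b-3p (flagged in PTU replicate 6) and miR-184 were included because they stood apart in 1 library.

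The erythroid list, with a median log2 fold change of 0.82, stood above the other miRNAs in PTU serum by camera with a preset correlation and not with an estimated one (adjusted p = 0.275 with an estimated correlation). PTU replicate 3 as the whole source of the list median is argued against by a median of 0.7875 without it (SE 0.195). However, camera's call ended there (adjusted p = 0.0691), and adjusted over the list alone 0 members passed. PTU replicate 6 stays open, with a median of 0.4396 without it (SE 0.241). There 7 of 7 members stayed higher and camera's adjusted p was 0.0103 (adjusted p = 0.382 with an estimated correlation). Both SEs are over the list members, which are not independent, and hold no spread between pups. So neither median was tested against that spread. Red cell RNA released into some samples remains open: with the ratio of miR-451-5p to miR-23a-3p as covariate, the median of the 6 other members went from 0.5942 to 0.3057 (SD over these members 0.34), and the ratio itself holds an erythroid miRNA. The thyroid state of the pups may also account for it and cannot be told apart from red cell lysis, because the data hold no measure of lysis independent of these miRNAs. The difference in the ratio between the groups did not pass (exact permutation p = 0.05661), but no value of it could have separated these explanations. Chance was not excluded: 15 of 100 splits of the 14 libraries gave a camera p as small as 0.000204, the smallest other being 2.95e-10.

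miR-543-3p and miR-495 had higher means in PTU serum, and the scaling as the source is argued against for miR-543-3p, whose lowest log2 fold change over 3 other scalings was 0.7179 (SE 0.20), but stays open for miR-495, whose lowest was 0.4239 (SE 0.21), too close to the bound set for the test. A rise of the whole Dlk1-Dio3 cluster as large as that of the pair is argued against by the 66 other members. They had a median log2 fold change of 0.05 with an SD of 0.23 over members. This lay below the 0.83 of miR-543-3p and the 0.53 of miR-495 by more than that SD, and 0 and 3 of the 66 were as high. Relative to the cluster median per library the pair were higher by 0.8088 and 0.4444, given without a p because the series title names them. For the same reason the excess of the pair is not independent evidence. The median of the 66 other members per library was higher in PTU by 0.067 on the log2 scale (exact two-sided permutation test, p = 0.51). So no rise of that median was shown between the pups. A small rise of the cluster stays open, because this test does not exclude one and camera's calls of it depended on the setting. A difference in thyroid state is a hypothesis for these miRNAs that was not tested apart from the groups.

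PTU replicate 6 stood apart from the other libraries, with the highest value of its group by Dixon's test for 21 of 357 miRNAs and the lowest for 11, where no other library had more than 4 of either. A low total over the listed miRNAs is argued against, as its 1192000 counts (to 4 digits) lay within the range of the other PTU libraries. The depth of the library itself is not given. RNA from platelets in that library may contribute and cannot be told apart. The platelet and endothelial list lay 0.97 above the median of the other libraries (log2). miR-223-3p, abundant in platelets, lay 0.77 above it, between the bounds set for the test. However, miR-199a-3p and miR-223-5p of the same list lay at -0.77 and -0.86. miR-223-3p is also in the leukocyte list, which lay at -0.20, so its value could not single out platelets. Other lists deviated in PTU replicate 6 too, the erythroid list at 0.81, the liver-enriched at 0.45, the epithelial at -0.57 and the X-linked miR-322-503 cluster at -0.49. These medians hide members that went the other way, and arms of 1 precursor could part. In the X-linked cluster miR-322-5p lay at 2.71 and miR-322-3p at -0.54. miR-199a-5p lay at 0.97, unlike miR-199a-3p, whereas both arms of miR-144 lay above (1.30 and 0.81). For miR-484 that library carried most of the group difference, which was 0.5624 without it and 2.17 with it, and no biological explanation was tested.

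In PTU replicate 6, miR-484 was at 1061 CPM where the other PTU libraries had 53.7 to 119 CPM. In that library miR-365-3p was at 418.3 CPM (others 170 to 249), miR-126a-3p at 8923 CPM (3367 to 4839), miR-222-3p at 225.7 CPM (41.9 to 64.5) and miR-29b-3p at 1512 CPM (42.9 to 164). The log2 fold change of miR-29b-3p was 2.01 with that library and -0.075 without it, and that of miR-222-3p 1.17 and 0.45. PTU replicate 5 was highest of its group for miR-203b-3p, at 285.6 CPM (others 38.8 to 113), and for miR-203a-3p, at 5889 CPM (1748 to 3173). PTU replicate 3 had the largest total, 2120000 counts to 3 digits, and the highest miR-542-3p, 2486 CPM (1171 to 1643). PTU replicate 1 had 222 CPM of miR-184 (10.5 to 59.1), whose log2 fold change was 1.88 with that library and 0.64 without it. Control replicate 6 had the lowest miR-451-5p, 1457 CPM (others 3813 to 5110), and the lowest log2 ratio of miR-451-5p to miR-23a-3p, -1.227 (0.012 to 0.58). Control replicate 1 had the lowest miR-199a-3p, 40530 CPM (51890 to 61920), and the highest miR-142-3p, 4548 CPM (1258 to 2142), and miR-144-5p, 731.2 CPM (166 to 397). Control replicate 3 was highest for miR-375-3p, at 161.8 CPM (37.9 to 91.4), and Control replicate 5 for miR-183-5p, at 977.6 CPM (438 to 688).

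The numbers of miRNAs and lists were set against 100 splits of the 14 libraries into groups of 8 and 6, the real one included. For miRNAs past an FDR of 0.05 the real number was 0, so all 100 splits gave as many by construction and the count says nothing about chance; the highest other gave 6. For the 47 miRNAs at an unadjusted p under 0.05, 4 of the 100 splits gave as many and the highest other gave 58. This share lay under the bound of 0.05 set for the test. The 100 were a random draw from 3003 splits, too few to place the share firmly under that bound, so chance was not firmly excluded. For the 2 lists past an adjusted p of 0.05, 69 of the 100 splits gave as many and the highest other gave 5, so chance was not excluded.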

How the results depend on the processing

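The exact test, the robust fit, the permutation test per miRNA and the list tests under other scalings, filters, covariates and left-out libraries (and, with an estimated correlation, the block) were chosen after the data were seen; the other settings were chosen before. Of 1320 values for the 44 named miRNAs under these settings, 1244 kept their direction and their side of the threshold, 9 passed it where they had not, and 67 changed direction. All values that changed direction belonged to miRNAs that passed no test. No miRNA passed with RLE, upper-quartile or no factors, with either filter, with limma-voom, with the robust fit, with any covariate, in the permutation test or at an FDR of 0.1. 2 miRNAs were higher in PTU by DESeq2, 3 by the likelihood ratio test and 3 by the exact test, and in these miR-543-3p had log2 fold changes of 0.81, 0.81 and 0.83. The cause was not tested. Leaving out each library in turn gave 0.75 to 0.89 for miR-543-3p and 0.35 to 0.60 for miR-495, and 0 to 1 miRNAs lower in PTU (miR-203b-3p, without PTU replicate 5).

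The number of lists past an adjusted p of 0.05 was 2 by camera. It was 1 with upper-quartile factors, 1 with either form of the label ID as covariate, 1 with the red cell ratio as covariate, 0 with an estimated correlation, 0 by fry, 1 by fry for either direction, and 0 to 6 with single libraries left out. With an estimated correlation it was 0 under each of these scalings, filters, covariates and left-out libraries. For the erythroid list the adjusted p was 0.817 with the ratio as covariate, 0.275 with an estimated correlation, 0.163 by fry, 0.378 by fry for either direction, and 8.95e-06 to 0.0691 with single libraries left out. For the epithelial list it was 0.0772 with upper-quartile factors, 0.0618 and 0.145 with the label ID as covariate (as a number, and up to 9 against 10 and over), and 0.468 with the ratio as covariate. It was 0.534 with an estimated correlation, 0.429 by fry, 0.341 by fry for either direction, and 0.00148 to 0.173 with single libraries left out. With single libraries left out, the median log2 fold changes of the lists ran as follows: imprinted Dlk1-Dio3 cluster -0.0052 to 0.10, brain-enriched 0.056 to 0.23, liver-enriched -0.28 to -0.028, striated muscle -0.13 to 0.042, erythroid 0.44 to 0.96, platelet and endothelial -0.13 to 0.22, leukocyte -0.16 to -0.05, pancreas 0.036 to 0.21, epithelial -0.38 to -0.15, let-7 family -0.09 to 0.021, X-linked miR-322-503 cluster -0.027 to 0.081, thyroid hormone-linked -0.026 to 0.10. The group difference in the red cell ratio ran from 0.56 to 1.03 with single libraries left out. The cause was not tested for any of these.

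The replicate numbers 1 to 6 occur in both groups but belong to separate litters, and the correlations of same-numbered libraries around their group means ran from -0.249 to 0.287, so the numbers were not taken as pairs. Only replicate 4 correlated best with its own number. With the replicate block, 0 miRNAs passed, 27 had an unadjusted p under 0.05 where 47 had without it, and 3 lists passed camera, the Dlk1-Dio3 cluster (adjusted p = 0.042) besides the erythroid and epithelial lists. With the block and an estimated correlation none of the 3 passed (adjusted p = 0.56, 0.555 and 0.555 with an estimated correlation). In the fit with the replicate block the values were 0.085 for miR-455-5p, -0.0051 for miR-365-3p, -0.0077 for miR-16-5p, -0.12 for miR-7b, -0.015 for let-7i-5p, 0.0065 for miR-542-3p.

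Other log2 fold changes that changed sign, for miRNAs that passed no test, were these. With upper-quartile factors the values were -0.048 for miR-431, -0.023 for miR-434-3p, -0.15 for miR-365-3p, -0.022 for miR-16-5p, -0.052 for miR-21-5p, -0.0044 for miR-126a-3p, -0.092 for miR-142-5p, -0.041 for let-7i-5p. With label IDs up to 9 set against 10 and over the values were -0.037 for miR-431, 0.016 for miR-122-5p, 0.0044 for miR-455-5p, -0.0067 for miR-16-5p, -0.060 for miR-142-5p, -0.0056 for let-7i-5p. With no factors the values were 0.0035 for miR-455-5p, 0.0029 for miR-375-3p, 0.042 for miR-542-3p. With the red cell ratio as covariate the values were 0.037 for miR-455-5p, -0.10 for miR-365-3p, 0.041 for miR-206-3p, -0.24 for miR-16-5p, -0.0078 for miR-21-5p, -0.0022 for miR-126a-3p, -0.46 for miR-142-5p, -0.0089 for miR-7a-5p, 0.094 for miR-375-3p, 0.0099 for miR-205, -0.093 for let-7i-5p. With limma-voom the values were -0.20 for miR-365-3p, -0.10 for miR-21-5p, -0.12 for miR-126a-3p. With the number in the label ID as covariate the values were -0.0095 for miR-365-3p, -0.028 for miR-142-5p. On mean log2 CPM, as the permutation test used, the values were -0.046 for miR-365-3p, -0.037 for miR-142-5p. With single libraries left out the ranges were miR-431 -0.074 to 0.10, miR-434-3p -0.043 to 0.12, miR-455-5p -0.15 to 0.022, miR-365-3p -0.26 to 0.11, miR-16-5p -0.042 to 0.19, miR-21-5p -0.13 to 0.19, miR-126a-3p -0.13 to 0.27, miR-142-5p -0.18 to 0.14, miR-375-3p -0.30 to 0.12, miR-7b -0.015 to 0.33, let-7i-5p -0.063 to 0.13, miR-542-3p -0.21 to 0.048. For miR-29b-3p, which had 2.01 with all libraries, the range was -0.075 (without PTU replicate 6) to 2.34. The cause was not tested. Depth limits scarce miRNAs, such as miR-7b at 25.1 CPM in controls. miR-451-3p, let-7c-1-3p and let-7a-1-3p were scarcer still, with means of 10.0, 10.5 and 16.7 CPM over all libraries.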

Other observations

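The correlation between arms was set out as a test before its result was seen; the count of miRNAs on one side of the control median and the miRNAs named here were chosen after the values were seen, and no miRNA passed an FDR of 0.05. All 6 PTU libraries lay above the control median for 11 of the 357 miRNAs and none did for 25. Over all 3003 splits of the libraries the mean was 30.2 such miRNAs (3 to 118), and 844 splits gave at least 36 (exact permutation p = 0.281), so their number was not unusual. Those not yet named include the following. miR-378a-3p, made from an intron of a metabolic coactivator gene, averaged 8732 ± 1067 CPM in PTU (SD, n = 6) and 10528 ± 642 CPM in controls (SD, n = 8), a log2 fold change of -0.27 ± 0.10 (SE; adjusted p = 0.258, edgeR). Both arms of miR-30a were lower, miR-30a-5p with -0.26 ± 0.11 and miR-30a-3p with -0.34 ± 0.12 (SE), and in 0 of 6 PTU libraries was either above the control median. miR-140-3p, a cartilage miRNA, had -0.41 ± 0.16 and the passenger arms let-7a-1-3p and let-7c-1-3p -0.57 ± 0.22 and -0.65 ± 0.28. Among those higher, miR-410-3p and miR-380-3p of the Dlk1-Dio3 cluster had 0.46 ± 0.16 and 0.53 ± 0.21, with 6 of 6 PTU libraries above the control median, whereas miR-381-3p of the same cluster had -0.45 ± 0.20 with 0 of 6.

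If the treatment acted on many precursors, the arms of a precursor were predicted to change together more than in other splits of the libraries. Across 94 precursors with both arms tested, the log2 fold changes of the arms had a Pearson r of 0.3362 and a Spearman rho of 0.202. These are across precursors, which are not independent replicates. As high an r was given by 55 of 100 splits of the libraries. The other splits had a median of 0.3518 and a highest of 0.6384. So the arms varied together as much in groupings that mix the treatments. The hypothesis is argued against only as the source of this correlation. A treatment effect on some precursors stays open, because an r over all 94 could not show it.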
